A study of Mus musculus with 17 samples.

How the data were processed

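RNA of 17 samples of the murine Bcr-Abl+ leukaemia cell line DA1-3b was analysed, each hybridised with Cy3 label to a 1-colour Agilent array. Per the labels, the cells (mouse strain C3H eOuJ) grew in DMEM with serum and were transfected with plasmids for p65/RelA or for parts of it. Groups were taken from the source name of each sample: wild-type p65 (WT, 4 arrays), the point mutant D361E (4 arrays), residues 1-361 (3 arrays), residues 362-549 (3 arrays) and both parts together (1-361+362-549, 3 arrays). The treatment protocol also names an empty plasmid, and samples with it were not analysed here, so WT is the common reference. Replicate numbers follow the order of deposit within each group, which is that of the leading number in the sample titles except in 1-361, where replicate 3 carries the lowest number. The labels do not say that the samples came from separate cultures, so each p-value measures the spread between these arrays, which may be partly technical, and the number of arrays limits the precision.

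The deposited files hold spot intensity values on a linear scale. Per the file headers, the arrays (design 026655, probe coordinates on build mm9) were read with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, which subtracted background and detrended each array in space. Low values were replaced by surrogates within that software, and no scaling between arrays was found in the deposited intensity values. The submitters' processing notes name the same software and version. The deposited table of values for the whole series equals the processed signal of each array (largest relative difference 0), so it gives the same values as the alternative without scaling. Each array holds 44397 spots, 43020 of them not controls, for 39429 probes.

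Processed signals were turned to log2 and the 75th percentile of each array was subtracted. Control spots and spots marked as outliers by the scanner software were left out, and the remaining spots of 1 probe were averaged. The 132 probes with no spot left on some array were left out. A probe was kept when it was well above background on every array of at least 1 group, which left 19768 probes (17591 passed on all 17 arrays and 19633 were dim on every array). Symbols came from the accession of each probe through a RefSeq table of assembly GRCm38.p6, used for names only. That table named 27508 probes, and 11921 kept the name in the array file. The brightest probe stood for each gene, which mattered for the 7145 symbols with several probes, and 15253 genes were tested. Different probes of a gene did not always move alike, and those of the large rises seen in 1 line are given with the observations.

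Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with data.table (version 1.17.8) for reading, in 1 model over the 5 groups. All 10 contrasts between groups were drawn from it, and an F-test covered the 4 contrasts against WT. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. Changes are given on the log2 scale as estimate ± SE, and group levels as mean ± SD of the log2 value relative to the 75th percentile. A gene dim on every array of 1 group has only a bound there. It is given as "at least N-fold", from the mean of the brighter group against the mean, per array of the dim group, of the higher of the lowest signal well above background and the probe's own signal. Private genes are those called against each of the other 4 groups.

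The genes named were chosen by a rule. Rela came first. Next came, among called genes with an ordinary symbol (11361 of the genes tested) whose groups did not overlap on any array, the 8 largest rises and the 8 largest falls for each contrast against WT, and the 5 and 5 largest for the other contrasts. Up to 4 called members with the smallest adjusted p followed from each gene list. The lists numbered 22, with 11 further lists of cell type markers. List shifts were tested with limma's camera at a preset correlation between genes of 0.01, again with a correlation estimated per list, and with fry, which tests whether the genes of a list move on balance 1 way. Of 220 list tests, 89 passed with camera, 10 of them with an estimated correlation, and fry called 33. Median, mean and test had the same sign in all 89 called list tests. Among the 131 others the sign differed in 32. For marker lists the sign differed in 0 of 36 called and in 12 of 64 other tests.

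The arrays came from 6 slides of 2 to 4 arrays, each with at least 2 groups, and all were scanned on 1 day, so a block for the day of scanning was not run. Slide was fitted as a fixed block, and changes were computed within each slide that held both groups. Other settings tried were quantile normalization, no scaling, normexp background correction with an offset of 50, other filters on dim probes, the mean of all probes, slide as a random block, the round of the title numbers as a block, a variance trend, array weights, the compared groups alone, and each array left out in turn. Comparisons, lists, the rule for names and these settings were fixed before the data were examined. Analyses without the 2 arrays farthest from their groups, and of the first 3 rounds alone, were chosen after seeing the data.

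The code was tested on simulated data in which 200 of 15253 genes were changed. For D361E against WT, 69% of genes changed by 1 on the log2 scale and 93% of those changed by 2 were recovered, with 8 false calls. The figures for 1-361+362-549 against WT were 62% and 92%, with 8 false calls, and for 1-361+362-549 against 362-549 they were 53% and 92%, with 9 false calls. A shifted list was recovered, and 0 of 20 random lists were called. The 75th percentile of the processed signal lay between 636 and 1214 across arrays, and 49.4% to 54.0% of spots were well above background.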

Results

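Gene expression was measured on 17 arrays of DA1-3b cells transfected with forms of p65/RelA. RelA is a subunit of the transcription factor NF-kB, with an N-terminal DNA-binding Rel homology domain and a C-terminal transactivation domain. The series design sets the genes regulated by wild-type p65 (WT, n = 4) against those regulated by the D361E mutant, described as non-cleavable (n = 4), and by the fragments that cleavage yields. The fragments were 1-361, 362-549 and both together (1-361+362-549), n = 3 each. Array brightness, as the 75th percentile of the processed signal, averaged 909 for WT, 781 for D361E, 774 for 1-361, 678 for 362-549 and 1042 for 1-361+362-549. Pairs of arrays within a group correlated across genes at 0.966 to 0.995, where genes are not independent replicates. Of 15253 genes tested, 1358 differed among the groups in the F-test over the contrasts with WT, and 469 did so with slide as a block. Without 1-361+362-549 replicate 1, 2 or 3 the count was 717, 717 and 2104.

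**Figure D1:**
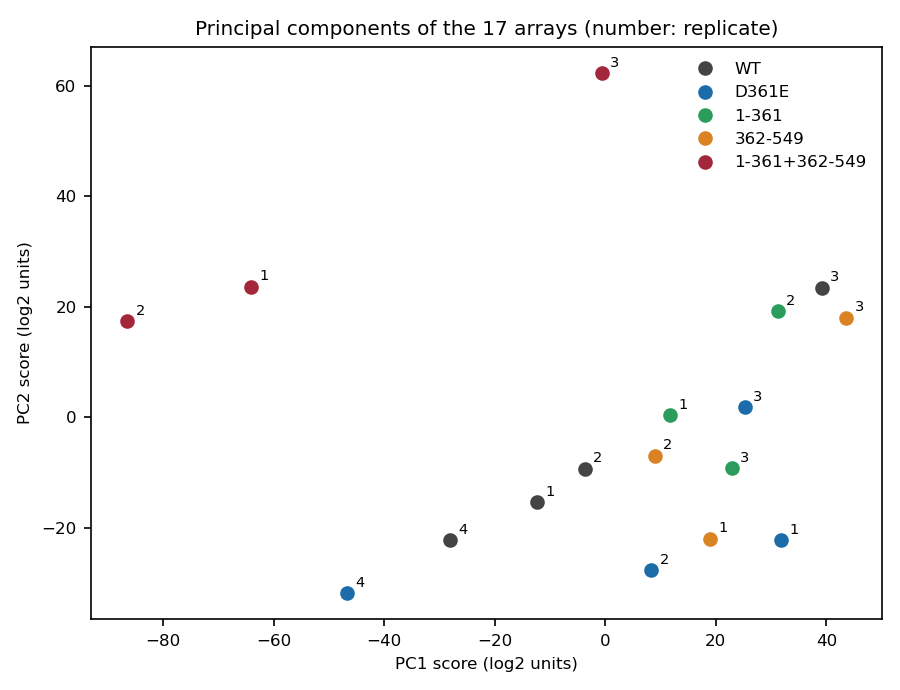
Principal components of the 17 arrays, with PC1 (39.1% of the variance) on the horizontal axis and PC2 (17.3%) on the vertical axis, both as scores in log2 units. Points are arrays, coloured by group and numbered by replicate; 1-361+362-549 replicates 1 and 2 lie at -64.1 and -86.5 on PC1, and replicate 3 lies at -0.64 on PC1 and 62.4 on PC2.

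Rela itself was read by 1 probe, at 5648070 to 5648129 on chromosome 19 of mm9. Its sequence, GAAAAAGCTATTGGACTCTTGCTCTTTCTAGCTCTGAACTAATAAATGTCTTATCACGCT, holds a polyadenylation signal and was taken to lie in the 3' untranslated region, which a coding plasmid would lack. With that position assumed and not looked up, the probe was not used to check the transfected constructs. Rela levels were 4.78 ± 0.08 (SD, n = 4) in WT, 4.74 ± 0.12 (n = 4) in D361E, 4.78 ± 0.05 (n = 3) in 1-361, 4.83 ± 0.03 (n = 3) in 362-549 and 4.86 ± 0.07 (n = 3) in 1-361+362-549. None of the 10 contrasts called Rela (limma adjusted p from 0.473 to 1), and the sign of its small differences turned with the scaling or background correction in 6 of them.

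**Figure D2:**
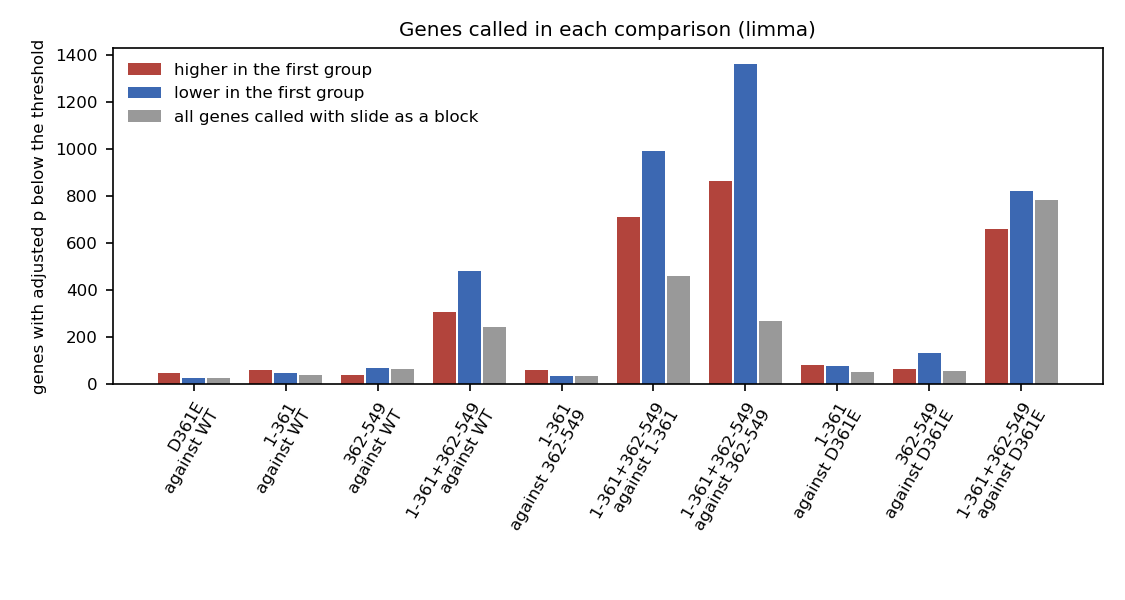
Number of genes called by limma in each of the 10 comparisons (vertical axis, genes; horizontal axis, comparison). Red and blue bars count genes higher and lower in the first group, and grey bars count all genes called with slide as a block; 1-361+362-549 against WT stands at 304 higher and 479 lower, and D361E against WT at 47 and 27.

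In cells with the non-cleavable D361E mutant, Ccl3, Hif1a and several cystatin-like genes stood higher than with WT p65. Ccl3, a macrophage chemokine and NF-kB target, rose by 2.42 ± 0.25 (adjusted p = 9.99e-05; 3 of 4 WT arrays well above background). Hif1a, the oxygen-regulated transcription factor, rose by 1.14 ± 0.11 (6.75e-05), from -0.26 ± 0.17 (n = 4) to 0.88 ± 0.09 (n = 4). The cystatin-like protease inhibitors Stfa1 and Cstdc4 rose by 2.84 ± 0.32 and 2.59 ± 0.27, and Stfa2l1 and Stfa2 were at least 3.50-fold and 3.28-fold higher. Stfa1 was well above background on 2 of 4 WT arrays. Slc4a5, a bicarbonate transporter, rose by 3.35 ± 0.27 (1.28e-05; 1 of 4 WT arrays well above background), and the long noncoding RNA Mirt2 was at least 6.51-fold higher. Ifitm6, an interferon-induced transmembrane protein, rose by 2.83 ± 0.39 (1 of 4 WT arrays well above background).

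Among the falls with D361E, the calcium channel gene Trpc6 fell by 2.97 ± 0.32 (adjusted p = 0.000108) and Itih3, an inter-alpha-trypsin inhibitor heavy chain, fell by 2.62 ± 0.26 (6.75e-05). The mast cell protease gene Cpa3 fell by 2.54 ± 0.33, and falls were also called for the slow troponin gene Tnni1 (-2.17 ± 0.21), the chaperone gene Clu (-1.55 ± 0.26) and the adaptor gene Grb7 (-1.51 ± 0.16). Map3k19 was at least 2.78-fold lower. Arl6ip1, Isg20 and Me1 were called lower and Prg2, Olr1 and Cxcr4 higher, at adjusted p from 0.0271 to 0.0374, and each lost its call without any of at least 6 of the 8 arrays.

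Of the 50 measured NF-kB target genes, 2 rose (Ccl3 and Olr1) and 0 fell with D361E, both over all genes and adjusted over the list alone, and the list did not shift (median 0.01, camera adjusted p = 0.866). The 43 interferon-stimulated genes shifted down, with a median of -0.19 (-0.22 with slide as a block, -0.35 to -0.23 within slides; adjusted p = 6.83e-09, and 0.00429 with an estimated correlation). Of these genes 1 fell over all genes (Isg20) and 3 fell adjusted over the list alone. The 31 integrated stress response genes had a median of -0.22 (-0.24 blocked, -0.14 to -0.02 within slides; 1.11e-05), and glycolysis and hypoxia genes one of -0.46 (-0.51 blocked, -0.77 to 0.01 within slides; 7.75e-05), although Hif1a of that list rose. Their adjusted p was 0.169 and 0.771 with an estimated correlation. Unfolded protein response genes (median -0.13, -0.07 blocked), STAT5 and BCR-ABL target genes (-0.13, -0.10 blocked), cholesterol synthesis genes (-0.20, -0.26 blocked) and cell cycle genes (-0.07, -0.10 blocked) passed only with the preset correlation (0.00414 to 0.0204). With an estimated correlation their adjusted p was 0.771 to 0.909. Of p53 target genes (median 0.16, 0.17 blocked, 0.08 to 0.39 within slides) 0 were called, and the median turned to -0.06 without scaling.

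D361E against WT called 74 genes of 15253, 47 higher and 27 lower, and for all 74 no array of 1 group overlapped the other. Calling selects for such a gap, here and below, so only the count over all genes can be set beside the chance share. Over all genes 552 did not overlap (chance share 2.86% for 4 against 4). An unadjusted limma p under 0.05 was found for 764 genes, where 762.7 are expected without any difference. For 1-361 against 362-549 this count was 844, and in the other comparisons 1175 to 4852. With slide as a block 24 genes were called, all 24 among the 74, while within each of the 2 slides with both groups 100% of the 74 kept their direction. The lack of overlap fixes that direction, here and for nearly all genes in the comparisons below, so it adds nothing to the blocked count. Without scaling 42.0% were higher, against 63.5%. Leaving out D361E replicate 1, 2 or 3 gave 48, 39 and 44 genes, and leaving out WT replicate 1 or 2 gave 39 and 40. Of the 22 named genes called, 16 kept the call without each array in turn, 11 kept it with the slide block, and all 22 kept their sign there. Among those that lost it with the block were Cpa3, Mirt2, Clu, Stfa2 and Ifitm6 (adjusted p = 0.146, 0.098, 0.082, 0.0683 and 0.0614). The changes of the 11 that lost it were 0.88 to 1.13 times those reported, while their median standard error went from 0.33 to 0.42 and the residual degrees of freedom from 12 to 7. Among marker lists of other cell types, mast cell or basophil genes fell with D361E (1 of 7 called, Cpa3; camera adjusted p = 4.4e-05, 0.0332 with an estimated correlation), although the median of -0.24 went from -0.47 to 0.27 within slides and was -0.03 blocked. The erythroid list rose (0.00958, 0.0407 with an estimated correlation), with a median of 0.02 that was -0.19 without scaling. Of its 5 genes 1 was called over all genes, the beta globin gene Hbb-bt (2.38 ± 0.29), and 2 were higher adjusted over the list alone. T cell, B cell and megakaryocyte lists passed with the preset correlation, and had adjusted p of 0.17, 0.0915 and 0.191 with an estimated correlation. By rotation (fry) the B cell list passed (0.0228) and the T cell and megakaryocyte lists did not (0.103 each).

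With the 1-361 fragment, the largest rise was that of Nsd1, a histone methyltransferase gene, at least 446-fold higher than in WT (adjusted p = 2.27e-10; 3.74 ± 0.28, n = 3, against -6.85 ± 0.35, n = 4). Its probe lay at 55419594 to 55419653 on chromosome 13 (mm9). Col4a5, a basement membrane collagen chain on chromosome X (138123547 to 138123606), was at least 19-fold higher, and Ogn, a secreted proteoglycan, at least 6.83-fold. Hbb-bh1, an embryonic beta-like globin, rose by 3.61 ± 0.37 (4.95e-05), and Rab11fip5, an endosome recycling gene, by 4.16 ± 0.60 (0.00168; 2 of 4 WT arrays well above background). Smco4, Stfa2l1 and the scavenger receptor gene Cd163l1 were at least 3.24-fold, 4.68-fold and 6.33-fold higher.

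Itih3 fell by 3.83 ± 0.28 with 1-361 (adjusted p = 1.48e-06), and the stress-induced gene Nupr1 fell by 2.53 ± 0.28 (0.000133). Lpgat1, an acyltransferase gene, fell by 2.39 ± 0.35 (0.00191). The IgE receptor chain gene Fcer1a was at least 2.3-fold lower, Map3k19 at least 2.1-fold and the kinase gene Prkd3 at least 1.64-fold. Cpa3 fell by 2.12 ± 0.35 (0.00628), a call that was lost without 1-361 replicate 3, and Fut1 was called at 0.0318.

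Of 50 NF-kB target genes, 4 fell and 0 rose over all genes with 1-361, and 8 fell adjusted over the list alone, with a median of -0.07 (-0.05 blocked, -0.30 to -0.05 within slides). The list passed at camera adjusted p = 0.000678, and had adjusted p = 0.167 with an estimated correlation and 0.26 with fry. Tnfaip3, the deubiquitinase A20 that limits NF-kB signalling, fell by 1.78 ± 0.24 (0.000812), from -0.28 ± 0.14 (n = 4) to -2.06 ± 0.11 (n = 3). The chemokine gene Ccl5 fell by 1.63 ± 0.29 (0.0121), a call lost without any 1 of the 1-361 arrays. The inhibitor gene Nfkbia fell by 1.01 ± 0.22 (0.0442), lost without 1-361 replicate 1 or 2 or any WT array. The lymphotoxin gene Lta fell by 1.72 ± 0.36 (0.038; 1 of 3 arrays of 1-361 well above background), lost without any 1-361 array or WT replicate 1 or 2. Of the 41 NF-kB pathway components 2 fell (Tnfaip3 and Nfkbia), also adjusted over the list alone (median -0.07, -0.07 blocked, -0.24 to -0.07 within slides; 0.000678, and 0.0449 with an estimated correlation).

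Of the 31 integrated stress response genes 4 fell with 1-361 (Nupr1, Cth, Atf5 and Eprs), and 5 fell adjusted over the list alone. Their median was -0.34 (-0.33 blocked, -0.63 to -0.26 within slides; 2.1e-13, and 0.016 with an estimated correlation). Cth, which makes cysteine, fell by 1.91 ± 0.29 (0.00334; 1 of 3 arrays of 1-361 well above background). The calls of Atf5 (0.0153; lost without 1-361 replicate 1 or 2 or WT replicate 3) and of Eprs (0.02; lost without any 1-361 array or WT replicate 1, 2 or 3) were less stable. Interferon-stimulated genes had a median of -0.19 (-0.17 blocked, -0.31 to -0.08 within slides; 0.000466, and 0.0449 with an estimated correlation), with 1 fall over all genes and 2 adjusted over the list alone. Cell cycle genes had a median of -0.12 (-0.09 blocked, -0.26 to 0.12 within slides; 0.00238), with adjusted p = 0.755 under an estimated correlation.

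The comparison of 1-361 with WT called 109 genes, 61 higher and 48 lower, without overlap between groups for any of the 109. Over all genes 1592 did not overlap (chance share 5.71% for 3 against 4). A slide block called 39, all among the 109, and 100% of the 109 kept their direction in both slides with both groups (fixed likewise). Without scaling 44.2% were higher, against 56.0%, and 62 were called without 1-361 replicate 1. Of 25 named genes called, 17 kept the call without each array in turn, 12 kept it with the slide block, and all 25 kept their sign there. With the block Tnfaip3 (-1.63 ± 0.27, adjusted p = 0.0514) and Nfkbia (-0.93 ± 0.27, 0.665) lost the call. So did Ccl5, Lta, Cth, Atf5 and Eprs (0.135, 0.594, 0.0904, 0.42 and 0.228) and Rab11fip5, Lpgat1, Fut1 and Cpa3 (0.102, 0.0987, 0.133 and 0.249). The changes of the 13 that lost it were 0.84 to 1.13 times those reported, and their median standard error went from 0.30 to 0.36. T cell markers moved with this group (Cd3d 0.63 ± 0.11 and Cd3g 1.99 ± 0.39 higher, with 2 of 4 WT arrays well above background for Cd3g; list 0.00522, 0.0046 with fry and 0.136 with an estimated correlation). So did megakaryocyte markers (Pf4 1.17 ± 0.20 higher, list 0.00522, 0.00956 with fry and 0.256 with an estimated correlation). Natural killer markers passed with the preset correlation alone (0 of 3 called, list 0.0441, 0.0945 with fry and 0.297 with an estimated correlation). Of the mast cell markers, Fcer1a and Cpa3 fell and Mcpt4 rose by 1.69 ± 0.34 (0.0293). The erythroid list passed with fry alone (0.0046; 0.772 with the preset correlation).

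With the 362-549 fragment, Epb41l3, Fndc4 and globin genes rose, and NF-kB target genes fell. Epb41l3, a membrane skeleton protein, rose by 10.33 ± 0.99 (adjusted p = 4.77e-05; 4.92 ± 0.12, n = 3, against -5.41 ± 1.90, n = 4, with 1 WT array well above background). Its probe lay at 69639235 to 69639294 on chromosome 17. The adult beta globin genes Hbb-bt and Hbb-b2 rose by 5.47 ± 0.32 and 5.37 ± 0.32 (1.78e-07 and 2.18e-07), Hbb-bs by 4.56 ± 0.59 (3 of 4 WT arrays well above background) and Hbb-bh1 by 3.46 ± 0.37. Globin probes of near-identical sequence can share signal. Fndc4, a secreted fibronectin-domain factor, was at least 14.4-fold higher, and the olfactory receptor gene Olfr165 at least 4.43-fold. Ttc25 was called higher at 0.026 (1 of 4 WT arrays well above background), and lost the call without any 362-549 array or WT replicate 1, 2 or 4.

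Itih3 was at least 20.2-fold lower with 362-549 than with WT (adjusted p = 8.54e-09), the cytokine gene Il13 at least 7.53-fold and Acod1, the itaconate-making enzyme of activated macrophages, at least 2.75-fold. Map3k19, Prkd3 and the paired receptor gene Pilrb1 were at least 1.92-fold, 1.5-fold and 1.77-fold lower. Pilra, of the same receptor family, fell by 2.65 ± 0.41 (0.00285; 1 of 3 arrays of 362-549 well above background).

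Of 50 NF-kB target genes 7 fell and 0 rose with 362-549, and 14 fell adjusted over the list alone. Their median was -0.23 (-0.28 blocked, -0.45 to -0.29 within slides; camera adjusted p = 1.87e-15, and 0.00365 with an estimated correlation). Tnfaip3 fell by 1.92 ± 0.24 (0.000508) and Nfkbia fell by 1.49 ± 0.22 (0.00193), from 5.03 ± 0.14 (n = 4) to 3.55 ± 0.48 (n = 3). Lta was at least 3.85-fold lower (0.00455). The interleukin gene Il6 fell by 1.62 ± 0.30 (0.0137), a call lost without 362-549 replicate 1 or 2 or WT replicate 2. The adhesion gene Icam1 fell by 1.24 ± 0.26 (0.0359), lost without 362-549 replicate 1 or 2 or any WT array. NF-kB pathway components counted 2 falls, 3 adjusted over the list alone (median -0.09, -0.07 blocked, -0.15 to -0.03 within slides; 0.00426), with adjusted p = 0.081 under an estimated correlation.

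**Figure D3:**
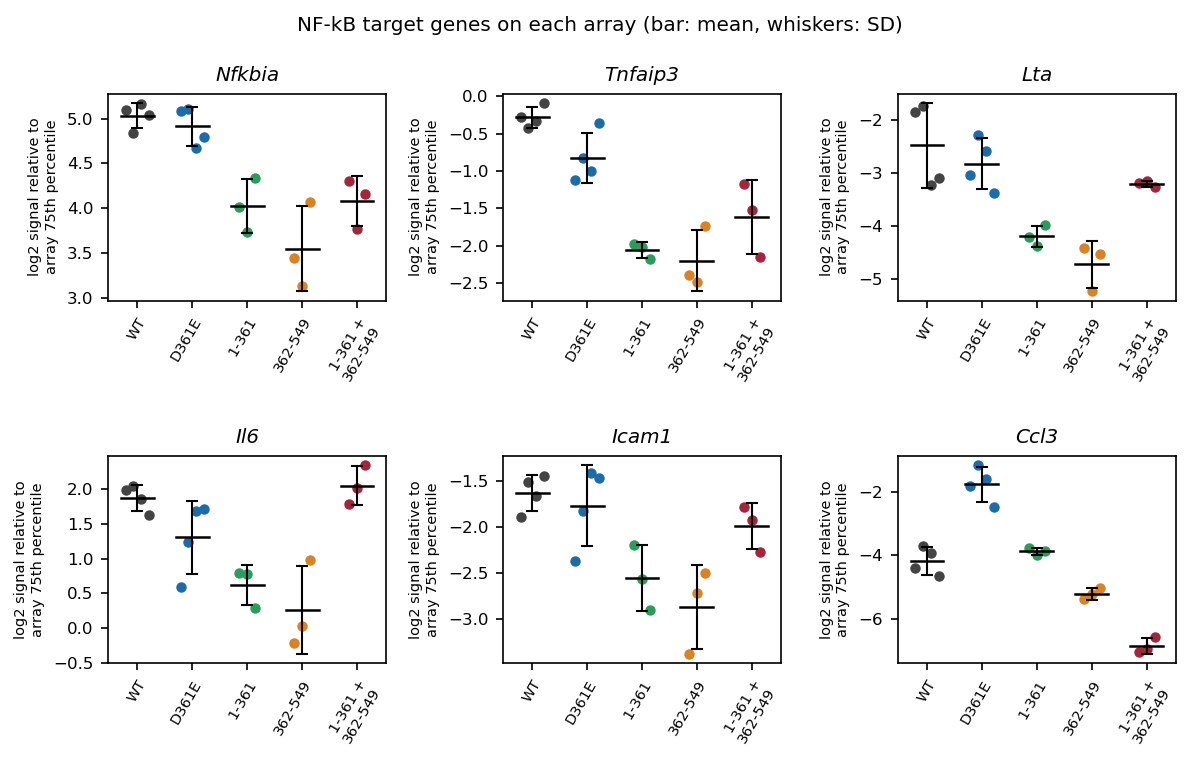
Log2 signal of 6 NF-kB target genes relative to the 75th percentile (vertical axes) on the 17 arrays, by group (horizontal axes). Points are arrays, bars means and whiskers SDs; Nfkbia stands at 5.03 ± 0.14 in WT and 3.55 ± 0.48 in 362-549, and Ccl3 at -4.17 ± 0.44 in WT and -1.75 ± 0.56 in D361E.

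Interferon-stimulated genes were lower with 362-549, with a median of -0.24 (-0.25 blocked, -0.30 to -0.14 within slides; 4.58e-08, and 0.00365 with an estimated correlation). Of 43, 2 fell and 0 rose, and 5 fell adjusted over the list alone. Gbp2, a guanylate-binding protein, was at least 1.84-fold lower (0.000476), and Gbp3 fell by 2.43 ± 0.44 (0.0116; 2 of 3 arrays of 362-549 well above background), a call lost without 362-549 replicate 3. Cytokine and chemokine receptor genes had a median of -0.24 (-0.24 blocked, -0.39 to -0.12 within slides; 6.06e-06, and adjusted p = 0.081 with an estimated correlation). Of these 25 genes 1 was called, Cxcr2, which fell by 1.63 ± 0.28 (0.00926; lost without 362-549 replicate 2). Integrated stress response genes (median -0.15, -0.13 blocked), apoptosis genes (-0.10, -0.05 blocked) and adhesion and integrin genes (-0.05, -0.09 blocked) passed only with the preset correlation, with adjusted p of 0.19, 0.19 and 0.312 with an estimated correlation.

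The comparison of 362-549 with WT called 109 genes, 40 higher and 69 lower, and 108 of them had no overlap between groups (1484 of all genes, chance share 5.71%). With slide as a block 65 were called, 64 of them among the 109, and 100% kept their direction in each of the 3 slides with both groups (fixed likewise). Without scaling 21.2% were higher, against 36.7%. Of 23 named genes called, 18 kept the call without each array in turn, 17 kept it with the slide block, and all 23 kept their sign there. With the block Tnfaip3 (-1.89 ± 0.25, adjusted p = 0.0081) and Nfkbia (-1.56 ± 0.25, 0.0264) kept the call, and Il6, Icam1, Gbp3, Cxcr2, Ttc25 and Pilrb1 lost it (0.0656, 0.179, 0.0601, 0.0817, 0.216 and 0.0696), with changes 0.94 to 1.03 times those reported and a median standard error of 0.37 in both fits. The erythroid marker list rose with this group (Hbb-bt called; list 0.00373, 0.0345 with an estimated correlation), with a median of 0.24 that was 0.28 blocked, -0.12 to 0.88 within slides and -0.18 without scaling. The T cell list (Cd3g 2.12 ± 0.39 higher; 2 of 4 WT arrays well above background) and the megakaryocyte list (0 of 6 called) passed with the preset correlation, and had adjusted p of 0.0214 and 0.215 with fry and 0.221 and 0.244 with an estimated correlation.

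Cells with both fragments differed from WT in many more genes than the other groups did, and Saa3, granzyme genes, Cpa3 and Tph1 fell. Saa3, an acute-phase protein and NF-kB target, fell by 7.40 ± 0.56 (adjusted p = 6e-07), from 4.34 ± 0.82 (n = 4) to -3.06 ± 0.57 (n = 3). The granzyme genes Gzmb (-6.64 ± 0.46, 2.08e-07) and Gzmc (-6.55 ± 0.36, 1.4e-08) fell. Cpa3 fell by 7.37 ± 0.35 (2.48e-09; 1 of 3 arrays with both fragments well above background), and Tph1, the serotonin-synthesis enzyme of mast cells, fell by 5.97 ± 0.26 (1.17e-09; also 1 of 3). The interleukin-2 receptor alpha chain gene Il2ra fell by 6.25 ± 0.45 (2 of 3), while Tnni1 and Itih3 were at least 24.1-fold and 30.1-fold lower.

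Macrod2, an ADP-ribose hydrolase gene, was at least 199-fold higher with both fragments (adjusted p = 1.27e-12; 2.57 ± 0.08, n = 3, against -6.83 ± 0.38, n = 4). Its probe lay at 142218642 to 142218701 on chromosome 2. The neutrophil-attracting chemokine gene Cxcl3 was at least 23.1-fold higher, Serpinb6e at least 21.3-fold, the inhibin subunit gene Inha at least 8.51-fold and Rtp4, an interferon-induced gene, at least 6.5-fold. Slc17a8, a vesicular glutamate transporter, rose by 4.38 ± 0.22 (5.58e-09; 1 of 4 WT arrays well above background). Usp17lc and Glt28d2 were at least 4.65-fold and 5.11-fold higher.

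**Figure D4:**
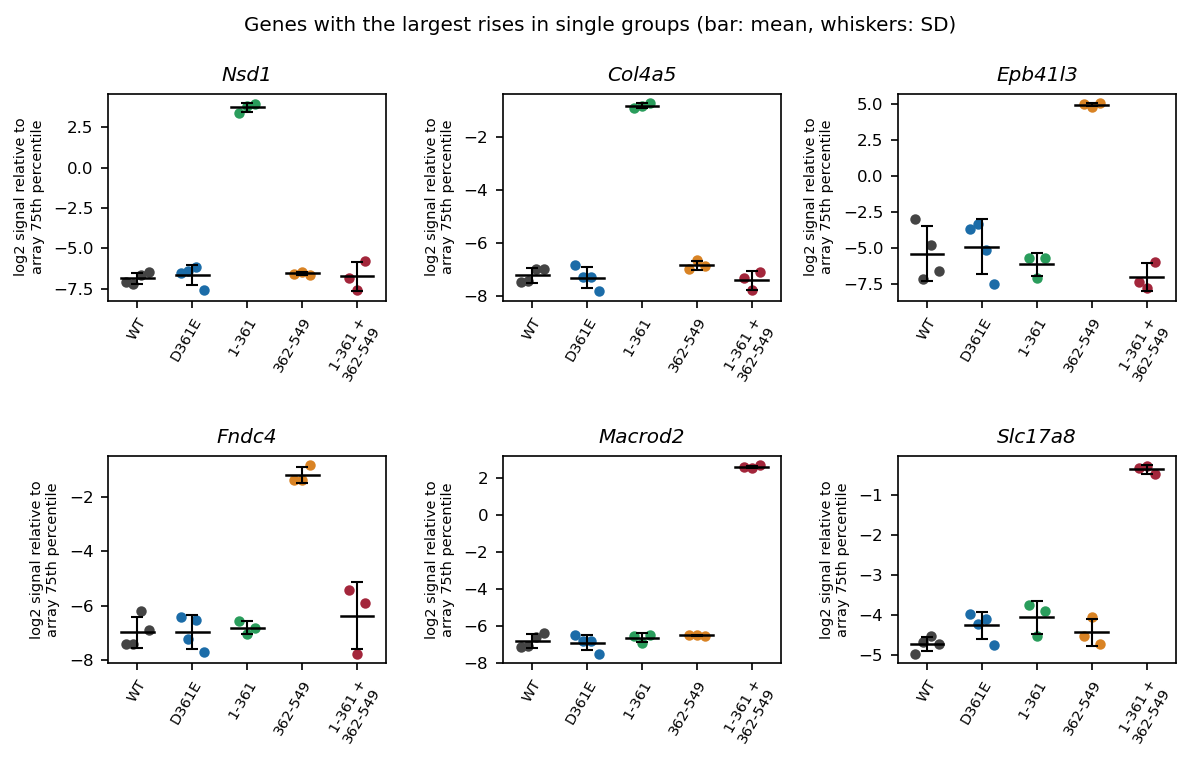
Log2 signal of 6 genes with large rises in 1 group, relative to the 75th percentile (vertical axes), on the 17 arrays by group (horizontal axes). Points are arrays, bars means and whiskers SDs; Nsd1 stands at 3.74 ± 0.28 in 1-361, Epb41l3 at 4.92 ± 0.12 in 362-549 and Macrod2 at 2.57 ± 0.08 in 1-361+362-549.

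NF-kB target genes moved both ways with both fragments, 3 higher and 10 lower of 50 (4 and 10 adjusted over the list alone). The median was -0.09 (-0.08 blocked, 0.05 within the 1 slide with both groups, 0.10 without scaling), and the camera adjusted p of 0.00879 became adjusted p = 0.287 with an estimated correlation and 0.00438 with fry. Beside Saa3 and Il2ra, the chemokine receptor gene Ccr7 fell by 3.92 ± 0.43 (3.07e-05), and Ccl3 was at least 2.06-fold lower. Among the NF-kB pathway components 2 rose and 3 fell, with Tnfaip3 (-1.34 ± 0.24, 0.00271) and Tnfrsf1b (-1.15 ± 0.21, 0.004; 2 of 3 arrays well above background) among the falls. The noncanonical subunit gene Relb rose by 0.95 ± 0.21 (0.0141), a call lost without 1-361+362-549 replicate 1 or 2, and Nfkbia was called lower at 0.0156, lost without 1-361+362-549 replicate 2. In the fit with slide as a block Tnfaip3 (-1.29 ± 0.31, adjusted p = 0.0936), Nfkbia (-0.84 ± 0.31, 0.382), Tnfrsf1b (-1.06 ± 0.27, 0.118) and Relb (1.11 ± 0.30, 0.141) lost the call while the changes stayed near those reported.

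Of 24 STAT5 and BCR-ABL target genes 8 fell and 0 rose with both fragments (1 higher and 9 lower adjusted over the list alone). Oncostatin M (Osm) fell by 2.52 ± 0.29 (5.75e-05), the cytokine signalling inhibitor gene Socs3 fell by 1.10 ± 0.15 (0.000195) and Id1 fell by 0.93 ± 0.13 (0.000411). The list had a median of -0.38 (-0.39 blocked, -0.43 within the slide; 2.97e-07), with adjusted p = 0.186 under an estimated correlation and 0.00189 with fry. Bcl2, the anti-apoptotic regulator, fell by 4.22 ± 0.24 (2.12e-08), from 3.69 ± 0.34 (n = 4) to -0.53 ± 0.18 (n = 3). Of the 36 apoptosis genes 1 rose and 2 fell. The beta chains of the interleukin-3 receptor, Csf2rb (-1.17 ± 0.15, 0.000105) and Csf2rb2 (-1.06 ± 0.15, 0.000424), fell, among 3 rises and 5 falls in 25 cytokine and chemokine receptor genes (5 and 7 adjusted over the list alone).

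Interferon-stimulated genes counted 9 rises and 2 falls of 43 with both fragments, 15 and 2 adjusted over the list alone (median 0.27, 0.28 blocked, 0.26 within the slide; 0.00174, and adjusted p = 0.132 with an estimated correlation and 0.00189 with fry). Mx2 rose by 1.63 ± 0.25 (0.000639), Parp9 by 0.83 ± 0.14 (0.00145) and Ifi47 by 0.68 ± 0.12 (0.00304), while Gbp4 was at least 5.31-fold lower. Of 31 integrated stress response genes 4 fell (Cth, at least 4.08-fold lower, Nupr1 at -2.59 ± 0.28, Atf5 at -1.46 ± 0.17 and Cebpb at -1.26 ± 0.18; 1 higher and 6 lower adjusted over the list alone). Their median of -0.07 (-0.13 blocked, -0.24 within the slide) turned to 0.13 without scaling, and the camera adjusted p of 0.00303 became adjusted p = 0.287 with an estimated correlation and 0.00552 with fry. Immediate early genes had 3 falls of 22 (Btg2 at -1.83 ± 0.23, 0.000128, and Ier3 at -0.97 ± 0.17 among them; 4 adjusted over the list alone; median -0.53, -0.55 blocked). The p53 target genes had 3 falls of 23 (6 adjusted over the list alone; median -0.29, -0.25 blocked), and adhesion and integrin genes 1 rise and 5 falls of 28 (1 and 7 adjusted over the list alone; median -0.36, -0.42 blocked). Osteopontin (Spp1) fell by 2.64 ± 0.29 (3.45e-05) and the integrin gene Itgb3 rose by 1.31 ± 0.24 (0.00343). These 3 lists passed with the preset correlation, and had adjusted p of 0.132, 0.287 and 0.132 with an estimated correlation and 0.0028, 0.023 and 0.00189 with fry.

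Of 60 cell cycle genes 2 rose with both fragments, among them the kinase gene Melk by 1.47 ± 0.28 (0.00531; list median 0.37, 0.35 blocked, 0.55 within the slide; 1.38e-05). Of 29 cholesterol synthesis genes 1 rose, Idi1 by 1.71 ± 0.29 (0.00187; list median 0.32, 0.16 blocked, 0.07 within the slide; 0.00212). Oxidative phosphorylation genes (1 of 60 higher, 0 adjusted over the list alone; median 0.22, 0.20 blocked), cytosolic heat shock genes (0 of 16 called; 0.32, 0.33 blocked) and replication-dependent histone genes (0 of 19 called; 0.28, 0.18 blocked, -0.23 within the slide) also passed with the preset correlation. These 5 lists had adjusted p = 0.494 with an estimated correlation and 0.158 to 0.173 with fry. MYC targets and ribosome biogenesis genes (0 of 47 called), DNA repair genes (0 of 56) and unfolded protein response genes (0 of 26) did not pass against WT, with adjusted p of 0.0555, 0.0709 and 0.586.

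**Figure D5:**
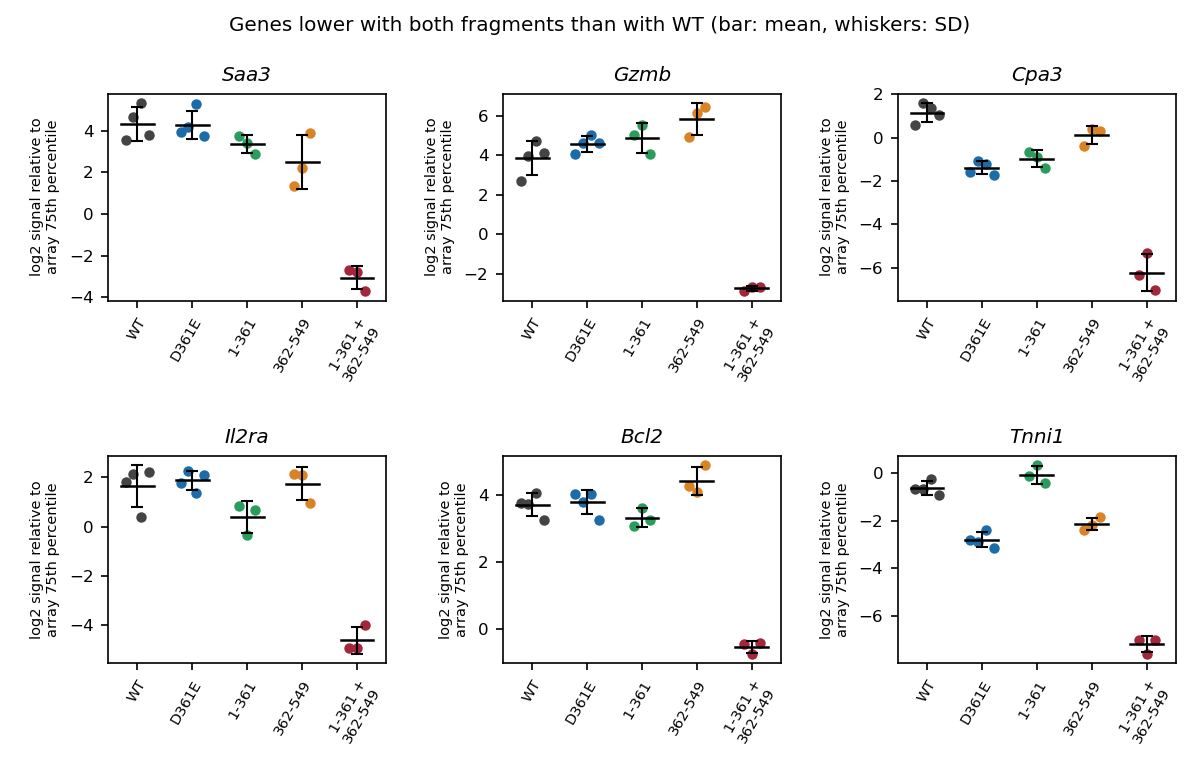
Log2 signal of 6 genes lower with both fragments than with WT, relative to the 75th percentile (vertical axes), on the 17 arrays by group (horizontal axes). Points are arrays, bars means and whiskers SDs; Saa3 stands at 4.34 ± 0.82 in WT and -3.06 ± 0.57 in 1-361+362-549, and Bcl2 at 3.69 ± 0.34 and -0.53 ± 0.18.

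Both fragments against WT called 783 genes, 304 higher and 479 lower, 762 of them without overlap between groups (2525 of all genes, chance share 5.71%). A slide block called 242, of which 239 were among the 783, and in the 1 slide with both groups 100% kept their direction (fixed likewise). Without 1-361+362-549 replicate 1, 2 or 3 the count was 469, 448 and 1238. Of 54 named genes called, 43 kept the call without each array in turn, 31 kept it with the slide block, and all 54 kept their sign there. Rtp4, Mx2, Parp9, Ifi47, Ier3, Melk, Idi1, Me1 and Itgb3 also lost the call with the block (adjusted p from 0.0508 to 0.193). The changes of the 23 that lost it were 0.74 to 1.18 times those reported, and their median standard error went from 0.18 to 0.26. Mast cell or basophil markers fell with this group, 4 of 7 over all genes (Cpa3, Fcer1a, Mcpt8 and Mcpt4) and 5 adjusted over the list alone (median -2.30, -2.18 blocked, -2.40 within the slide, -0.57 after normexp; 1.03e-06, and 0.0116 with an estimated correlation). Monocyte or macrophage markers (Adgre1 at least 10.6-fold lower; 0.000153), megakaryocyte markers (Pf4 2.20 ± 0.20 higher; 0.00679) and natural killer markers (Gzmb lower; 0.00858) passed with the preset correlation and with fry (0.000273, 0.000756 and 0.000567), not with an estimated correlation (adjusted p = 0.0933, 0.141 and 0.141). T cell, B cell and erythroid lists passed with fry (0.00189, 0.00129 and 0.00274) but not with the preset correlation (0.0549, 0.0549 and 0.243) or an estimated one (0.168, 0.141 and 0.267). Of these genes Cd3d (-0.95 ± 0.11) and Klf1 (-0.84 ± 0.18) fell, Hbb-bt (1.33 ± 0.32) and Epor (0.44 ± 0.11) rose, and Cd3g was at least 1.13-fold lower. Endothelial, neutrophil and progenitor lists passed in none of the 10 comparisons (smallest adjusted p 0.491, 0.378 and 0.515), and 0 fibroblast markers were measured.

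Ribosomal protein genes, 76 in number, gave list calls that rested on the scaling. Their medians against WT were 0.18 for D361E, 0.27 for 1-361, 0.42 for 362-549 and -0.21 for both fragments, with camera adjusted p from 1.18e-30 to 1.63e-06 but 0.19 to 0.771 with an estimated correlation. Of the 76 genes 0 were called over all genes against WT, and 49 rose with 362-549 adjusted over the list alone. Under quantile normalization, no scaling or normexp the medians lay between -0.04 and 0.03, and the sign for D361E turned without scaling. Without scaling the median of all genes itself shifted by -0.19 for D361E, -0.19 for 1-361, -0.36 for 362-549 and 0.23 for both fragments against WT. Glutathione and NRF2 target genes and MHC class I and II genes passed with camera in none of the 10 comparisons (smallest adjusted p 0.168 and 0.0872), although the MHC list passed with fry for both fragments against 1-361 (0.0227), with Me1 lower in D361E and with both fragments.

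The fragments were compared with each other. Nsd1, Col4a5, Rab11fip5, Ogn and Smco4 were at least 334-fold, 14.2-fold, 9.16-fold, 5.12-fold and 2.42-fold higher with 1-361 than with 362-549. Epb41l3 was at least 825-fold lower, Fndc4 at least 11.8-fold, Olfr165 at least 3.62-fold and Fcer1a at least 2.63-fold. Nupr1 fell by 2.86 ± 0.30 (adjusted p = 0.000119). Of NF-kB target genes 1 was higher, the lipoprotein receptor gene Olr1 (0.0274; 1 of 3 arrays of 362-549 well above background; lost without any 362-549 array or 1-361 replicate 1 or 2), and 4 were higher and 1 lower adjusted over the list alone. That list had a median of 0.29 (0.28 blocked, 0.28 within the slide; 7.41e-06, and adjusted p = 0.161 with an estimated correlation). Socs3 fell by 0.93 ± 0.16 (0.0103; lost without 362-549 replicate 3 or 1-361 replicate 1 or 2). The other lists called here, integrated stress response, STAT5 and BCR-ABL target, immediate early, ribosomal protein, histone and receptor genes, had adjusted p from 0.241 to 0.733 with an estimated correlation.

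In all, 96 genes were called between 1-361 and 362-549, 61 higher and 35 lower in 1-361, without overlap for any of the 96 (1605 of all 15253 genes, chance share 10% for 3 against 3). A slide block called 35, of which 34 were among them, and 100% kept their direction in the 1 slide with both groups (fixed likewise). Without scaling 78.8% were higher, against 63.5%. Leaving out 362-549 replicate 1, 2 or 3 gave 62, 55 and 59 genes, and leaving out 1-361 replicate 1 or 2 gave 51 and 48. Of 13 named genes called, 10 kept the call without each array in turn and 9 with the slide block, where Rab11fip5, Olr1 and Socs3 lost it (adjusted p = 0.187, 0.215 and 0.304; changes of the 4 that lost it 0.86 to 1.17 times those reported). Megakaryocyte markers were higher in 1-361 (Pf4 by 1.85 ± 0.22 and Ppbp by 3.14 ± 0.55; list 1.69e-07, and 0.0144 with an estimated correlation; median 0.40, 0.45 blocked), and erythroid markers were lower (Hbb-bt at -2.31 ± 0.34 and Klf1 at -0.91 ± 0.19; 3.11e-05, and 0.006 with an estimated correlation; median -0.65, -0.48 blocked). Mcpt4 was higher by 2.29 ± 0.37.

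Both fragments together were next set against each fragment alone. Relative to 1-361, Macrod2 was at least 162-fold and Cxcl3 at least 17.7-fold higher, and Nsd1 was at least 497-fold lower. Gzmc fell by 8.99 ± 0.39 (adjusted p = 7.24e-10) and the Fc receptor gamma chain gene Fcer1g fell by 7.55 ± 0.21 (6.86e-12), and Gzmb (-7.62 ± 0.49), Saa3 (-6.41 ± 0.60), Il2ra (-5.00 ± 0.47; 2 of 3 arrays with both fragments well above background) and Bcl2 (-3.84 ± 0.26) were lower. Relb rose by 1.51 ± 0.23 (0.000623) and Nfkb2, the p100 precursor gene, by 1.01 ± 0.20 (0.00588). Interferon-stimulated genes counted 18 rises and 1 fall of 43, 21 and 2 adjusted over the list alone (median 0.52, 0.43 blocked, 0.35 to 0.61 within slides; 2.2e-05, and 0.0398 with an estimated correlation), with Parp9 higher by 1.07 ± 0.15 and Mx2 by 1.55 ± 0.26. Of STAT5 and BCR-ABL target genes 1 rose and 8 fell (median -0.50, -0.50 blocked), and of cell cycle genes 6 rose (0.49, 0.44 blocked). Both lists had adjusted p = 0.432 with an estimated correlation. Ribosomal protein genes counted 17 falls (median -0.47), but 1, 0 and 0 with quantile normalization, no scaling and normexp and 0 with the slide block.

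That comparison called 1701 genes, 711 higher and 990 lower, 1680 without overlap (4579 of all genes, chance share 10%). A slide block called 460, of which 449 were among them, and 99.7% to 100% kept their direction within the 2 slides with both groups (fixed likewise for the genes without overlap). Without scaling 86.3% were higher, against 41.8%, with the median of all genes at 0.39. The count fell to 637 and 591 without 1-361+362-549 replicate 1 or 2 and to 785, 810 and 967 without 1-361 replicate 1, 2 or 3, and rose to 3888 without 1-361+362-549 replicate 3. Of 70 named genes called, 42 kept the call without each array in turn and 35 with the slide block, where Nfkb2 lost it (adjusted p = 0.0612; changes of the 35 that lost it 0.85 to 1.09 times those reported). Mast cell, monocyte, T cell, B cell and natural killer lists passed with the preset correlation and with fry (7.8e-06 to 0.00017), not with an estimated correlation (adjusted p = 0.0862), with Cpa3 (-5.25 ± 0.38; 1 of 3 arrays with both fragments well above background) lower and Adgre1 and Cd3g at least 7.37-fold and 4.47-fold lower.

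Relative to 362-549, Macrod2 was at least 149-fold higher with both fragments, and Cxcl3, Serpinb6e, Inha and Rtp4 were at least 17.3-fold, 16-fold, 6.37-fold and 4.87-fold higher. Epb41l3 was at least 1124-fold lower and the receptor kinase gene Ryk at least 19.5-fold. Gzmc fell by 9.04 ± 0.39 (adjusted p = 1.3e-09), and Gzmb (-8.59 ± 0.49), Il2ra (-6.35 ± 0.47; again 2 of 3), Saa3 (-5.55 ± 0.60), Bcl2 (-4.93 ± 0.26) and Socs3 (-1.60 ± 0.16) were lower. Cxcr2 rose by 2.57 ± 0.30 (4.9e-05), Il2rg by 1.49 ± 0.23 (0.000716) and Relb by 1.62 ± 0.23. Interferon-stimulated genes counted 21 rises and 1 fall, also adjusted over the list alone (median 0.64, 0.59 blocked; 1.35e-06, and 0.0156 with an estimated correlation), with Mx2 higher by 2.16 ± 0.26 and Isg20 by 1.82 ± 0.27. NF-kB target genes went both ways, 12 higher and 8 lower (16 and 9 adjusted over the list alone; median 0.32; 0.104, not passing). Immediate early genes counted 6 falls (median -0.69, -0.57 blocked), and STAT5 and BCR-ABL target genes 1 rise and 8 falls (-0.44, -0.42 blocked, 0.16 without scaling), with adjusted p of 0.273 and 0.499 under an estimated correlation. Ribosomal protein genes counted 59 falls (median -0.62), but 1, 0 and 2 calls with quantile normalization, no scaling and normexp and 0 with the slide block.

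No slide held both of these groups, so nothing could be compared within slides there. The comparison called 2223 genes, 863 higher and 1360 lower, 2172 without overlap (4415 of all genes, chance share 10%). A slide block called 269, of which 265 were among the 2223. Higher genes made up 38.8%, against 94.2% without scaling, where the median of all genes was 0.58, and 50.03% and 50.16% with quantile normalization and normexp. The count was 972, 879 and 4038 without 1-361+362-549 replicate 1, 2 or 3 and 1437 and 1116 without 362-549 replicate 1 or 3. Of 72 named genes called, 48 kept the call without each array in turn and 28 with the slide block, where Rtp4 and Il2rg lost it (adjusted p = 0.246 and 0.0865; changes of the 44 that lost it 0.67 to 1.3 times those reported). T cell, B cell, monocyte, mast cell, megakaryocyte and natural killer lists passed with the preset correlation and with fry (1.54e-06 to 6.18e-05), not with an estimated correlation (adjusted p from 0.125 to 0.161), with Cpa3 (-6.33 ± 0.38; 1 of 3 arrays with both fragments well above background) lower, Adgre1 and Cd3g at least 20.8-fold and 4.915-fold lower and Pf4 higher by 2.88 ± 0.22. The erythroid list, with Hbb-bt at -4.14 ± 0.34, passed with fry (3.38e-06) but not with the preset or an estimated correlation (0.133 and 0.161).

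Each fragment was also set against the D361E mutant. With 1-361, Nsd1, Col4a5 and Ogn were at least 483-fold, 20.6-fold and 7.39-fold higher, and Trpc6 rose by 3.94 ± 0.34 (adjusted p = 1.01e-05). The haptoglobin gene Hp was at least 5.72-fold lower and Prkd3 at least 2.18-fold. Padi4, which converts arginine to citrulline in histones, fell by 2.97 ± 0.24 (5.47e-06), and Pilra (-2.84 ± 0.41), the smooth muscle actin gene Actg2 (-2.56 ± 0.32) and Hif1a (-1.33 ± 0.12, 1.54e-05) were lower. Of NF-kB target genes 3 fell, Ccl3 (-2.12 ± 0.27, 0.000775), Ccl5 (-1.69 ± 0.29, 0.00868; lost without 1-361 replicate 1) and Tnfaip3 (-1.23 ± 0.24, 0.0172; lost without D361E replicate 2 or 4 or any 1-361 array), with 1 higher and 9 lower adjusted over the list alone. The list had a median of -0.23 (-0.17 blocked, -0.23 to -0.05 within slides; 9.21e-05, and adjusted p = 0.188 with an estimated correlation). Glycolysis and hypoxia genes had a median of 0.65 (0.67 blocked, 0.54 to 1.53 within slides), with 1 rise and 2 falls, 5 and 2 adjusted over the list alone (9.21e-05, and adjusted p = 0.786 with an estimated correlation). Other lists called here had adjusted p from 0.188 to 0.786 with an estimated correlation.

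Against D361E, 1-361 gave 156 called genes, 81 higher and 75 lower, without overlap for any of the 156 (1513 of all genes, chance share 5.71%). The slide block called 49, all among them, and 100% kept their direction in both slides with both groups (fixed likewise). Without 1-361 replicate 1, 2 or 3 the count was 81, 81 and 94. Of 23 named genes called, 15 kept the call without each array in turn and 12 with the slide block, where Tnfaip3, Ccl5 and Hp lost it (adjusted p = 0.218, 0.103 and 0.0563; changes of the 11 that lost it 0.91 to 1.03 times those reported). Megakaryocyte markers were higher in 1-361 (5.67e-07, and 0.0372 with an estimated correlation; median 0.92, 0.87 blocked) and B cell markers lower (0 of 2 called; 0.00752, and 0.0389 with an estimated correlation; median -0.49, -0.55 blocked). Cd3g was higher by 2.16 ± 0.39 (1 of 4 D361E arrays well above background), Mcpt4 was higher by 2.94 ± 0.34 and Fcer1a was at least 1.96-fold lower.

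With 362-549, relative to D361E, Acod1 was at least 10.1-fold lower (adjusted p = 3.01e-09), Hp at least 5.24-fold and the dendritic cell integrin gene Itgax at least 9.81-fold (0.00894; lost without 362-549 replicate 1). Epb41l3 rose by 9.86 ± 0.99 (4.38e-05; 2 of 4 D361E arrays well above background), Ryk by 3.42 ± 0.41 and Socs3 by 1.13 ± 0.15 (0.00045), and Fndc4 was at least 15.6-fold higher. Of NF-kB target genes 9 fell and 0 rose, and 15 fell adjusted over the list alone (median -0.24, -0.29 blocked, -0.49 within the slide; 1.86e-13, and 0.00674 with an estimated correlation). Ccl3 was at least 7.41-fold lower, Olr1 fell by 2.21 ± 0.26 (0.000166; 1 of 3 arrays of 362-549 well above background), and Nfkbia (-1.36 ± 0.22, 0.00322) and the lymphotoxin beta gene Ltb (-1.33 ± 0.23, 0.00574) were lower. Tnfaip3 fell by 1.38 ± 0.24 (0.00656), a call lost without 362-549 replicate 2. Hif1a fell by 1.31 ± 0.12 (1.86e-05). Other lists called here had adjusted p from 0.312 to 0.645 with an estimated correlation.

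In total 196 genes were called between 362-549 and D361E, 63 higher and 133 lower, without overlap for any of the 196 (1462 of all genes, chance share 5.71%). With slide as a block 55 were called, 54 of them among the 196, and 100% kept their direction in the 1 slide with both groups (fixed likewise). Without scaling 19.3% were higher, against 32.1%. The count was 107 and 124 without 362-549 replicate 2 or 3 and 119 without D361E replicate 2. Of 23 named genes called, 15 kept the call without each array in turn and 11 with the slide block, where Nfkbia, Tnfaip3, Ltb, Socs3, Hp and Itgax lost it (adjusted p = 0.113, 0.164, 0.102, 0.079, 0.0674 and 0.258; changes of the 12 that lost it 0.83 to 1.12 times those reported). B cell markers passed with the preset correlation and with fry (0 of 2 called; 0.00984 and 0.00124), not with an estimated correlation (adjusted p = 0.062), while Hbb-bt was higher by 3.09 ± 0.32 and Cd3g by 2.30 ± 0.39 (1 of 4 D361E arrays well above background). The erythroid list passed with fry alone (0.000103; 0.137 with the preset correlation).

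Both fragments were last set against D361E. Macrod2 was at least 215-fold higher, Gzmc fell by 8.15 ± 0.36 (adjusted p = 1.11e-09), and Gzmb (-7.34 ± 0.46), Saa3 (-7.34 ± 0.56), Il2ra (-6.49 ± 0.45; 2 of 3 arrays with both fragments well above background) and Bcl2 (-4.30 ± 0.24) were lower. Padi4 and Itgax were at least 35.9-fold and 14.6-fold lower. Of NF-kB target genes 4 rose and 12 fell (6 and 14 adjusted over the list alone), with Ccl3 at least 11-fold lower and Ccl4 at -4.36 ± 0.39. That list had a median of -0.02 (-0.03 blocked, -0.26 to 0.08 within slides, 0.39 without scaling; 0.0451, and adjusted p = 0.549 with an estimated correlation). Relb and Nfkb2 rose by 1.26 ± 0.21 (0.00112) and 1.04 ± 0.19 (0.00232). Interferon-stimulated genes counted 17 rises and 2 falls, 22 and 2 adjusted over the list alone (median 0.67, 0.70 blocked, 0.52 to 0.67 within slides; 8.94e-07, and 0.0156 with an estimated correlation), with Isg20 higher by 2.21 ± 0.25, Mx2 by 2.07 ± 0.25 and Parp9 by 1.25 ± 0.14. Of cell cycle genes 9 rose (median 0.44, 0.45 blocked), of cholesterol synthesis genes 3 (0.50, 0.39 blocked; Idi1 by 1.93 ± 0.29), and of p53 target genes 6 fell (-0.28, -0.30 blocked, 0.13 without scaling; Btg2 at -2.48 ± 0.23). These lists had adjusted p of 0.549, 0.549 and 0.404 with an estimated correlation.

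That last comparison called 1478 genes, 658 higher and 820 lower, 1337 without overlap (2723 of all genes, chance share 5.71%). With slide as a block 782 were called, 763 of them among the 1478, and 99.5% to 100% kept their direction within the 3 slides with both groups (fixed likewise for the genes without overlap). Without scaling 86.1% were higher, against 44.5%, with the median of all genes at 0.41. The count was 861, 890 and 2455 without 1-361+362-549 replicate 1, 2 or 3 and 953 and 2747 without D361E replicate 2 or 4. Of 61 named genes called, 43 kept the call without each array in turn and 41 with the slide block (changes of the 20 that lost it 0.87 to 1.03 times those reported). The marker lists called here passed with the preset correlation and with fry (1.27e-05 to 5.82e-05), not with an estimated correlation (adjusted p from 0.0847 to 0.158), with Cpa3 (-4.83 ± 0.35; 1 of 3 arrays with both fragments well above background) lower, Adgre1 at least 14.2-fold lower, and Gp1ba higher by 2.12 ± 0.23 and Pf4 by 1.91 ± 0.20. The erythroid list passed with fry alone (0.0183; 0.616 with the preset correlation).

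Some genes were called in the same direction in several contrasts against WT. Itih3, Map3k19, Grb7 and an unnamed RIKEN gene were lower in all 4, and Hbb-bt was higher in all 4, at 2.38, 3.16, 5.47 and 1.33 for D361E, 1-361, 362-549 and both fragments. For the pairs of contrasts, the same direction was called for 22 genes with D361E and 1-361, 24 with D361E and 362-549, 19 with D361E and both fragments, 35 with 1-361 and 362-549, 35 with 1-361 and both, and 31 with 362-549 and both. These contrasts share the WT arrays. At an unadjusted p under 0.01 the pairs shared 63, 61, 49, 108, 100 and 59 genes. Simulated unchanged groups against 1 simulated WT group shared 20.1, 19.4, 19.4, 18.1, 17.9 and 18.0 on average over 100 simulations. All simulated values, WT included, were independent noise, without the correlation within rounds or between genes, so they are only a rough baseline. Independent lists of the sizes called would share 0.085 to 2.17 genes per direction. With the WT arrays split between the contrasts, the overlaps averaged 15, 14.5, 9.67, 22.5, 16.2 and 16 genes. Opposite directions were called for 2, 5, 21, 1, 13 and 20 genes.

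Private genes numbered 4 higher and 1 lower for WT, 16 and 1 for D361E, 21 and 3 for 1-361, 12 and 16 for 362-549, and 197 and 317 for both fragments.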

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

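The items below were tested after the results were seen, by the gap of the outermost of 4 arrays to its nearest neighbour relative to the range of the group. Of 136 sets of 4 arrays tested (array measures, and named genes within WT and D361E), 4 exceeded Dixon's 95% critical value, where chance flags about 1 in 20, or 6.8 sets. The percent of spots well above background in WT gave a ratio of 0.875, with WT replicate 4 at 49.43 and the others at 51.8 to 52.14. Arl6ip1 in WT gave 0.901, with replicate 3 at -1.67 and the others at -0.90 to -0.81. Ttc25 in WT gave 0.94, with replicate 3 at -4.35 and the others at -6.67 to -6.53. Olr1 in D361E gave 0.84, with replicate 1 at -2.79 and the others at -2.21 to -2.10. The number of flags was below that given by chance, and no cause was tested.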

How the results depend on the processing

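All but the 2 alternatives named above were fixed in advance. Counts are of called genes, in the order D361E, 1-361, 362-549 and 1-361+362-549 against WT, then 1-361 against 362-549, 1-361+362-549 against 1-361 and against 362-549, and 1-361, 362-549 and 1-361+362-549 against D361E. The counts reported were 74, 109, 109, 783, 96, 1701, 2223, 156, 196 and 1478, and 1358 for the F-test. Quantile normalization, normexp background correction, the mean of probes, slide as a random block (correlation -0.052), and an intensity trend with robust variances left each count within 1.5 times of these. For the counts that moved by more, the cause was not tested.

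With slide as a fixed block the counts were 24, 39, 65, 242, 35, 460, 269, 49, 55 and 782, and 469 for the F-test. With the replicate block (rounds by title number) they were 248, 206, 194, 4687, 260, 5636, 6078, 462, 543 and 6070, and 5510 for the F-test. The round block was not used for the results reported, since the pairing rule was not met (correlation above 0.1 in 24 of 31 pairs, mean 0.33, lowest -0.18). Array weights gave 1995, 1034, 516, 9813, 163, 8983, 7978, 741, 621 and 10622, and 12255 for the F-test. Their estimation stopped before convergence, with a weight of 76.3 for 1-361+362-549 replicate 1 against 0.147 to 3.94 for the others, so these counts say nothing about stability.

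Without scaling, 432 genes were called for 1-361+362-549 against WT, 5461 for it against 362-549, 91 for 1-361 against D361E and 2605 for 1-361+362-549 against D361E. With no filter on dim probes the counts were 45 for D361E against WT, 751 for 1-361+362-549 against 1-361, 1210 for it against 362-549 and 839 for the F-test. With probes well above background on all 17 arrays they were 34, 61 and 51 for D361E, 1-361 and 362-549 against WT, 41 for 1-361 against 362-549, and 97 and 115 for 1-361 and 362-549 against D361E. Requiring a 2-fold change left 415, 684, 834 and 685 genes for 1-361+362-549 against WT, 1-361, 362-549 and D361E, and 593 for the F-test.

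Fitted on only the 2 groups compared, the counts were 43 for D361E against WT, 63 for 362-549 against WT, 424 for 1-361+362-549 against WT, 60 for 1-361 against 362-549, 544 and 509 for 1-361+362-549 against 1-361 and 362-549, and 98, 98 and 652 for 1-361, 362-549 and 1-361+362-549 against D361E. Without the 2 arrays farthest from their groups they were 194 for 362-549 against WT, 2340 for 1-361+362-549 against WT, 147 for 1-361 against 362-549, 5182, 5285 and 5435 for 1-361+362-549 against 1-361, 362-549 and D361E, and 3631 for the F-test. With rounds 1 to 3 alone, 2722 genes were called for 1-361+362-549 against D361E. Leaving out 1 array at a time gave 39 to 78, 62 to 106, 78 to 111, 448 to 1238, 48 to 67, 591 to 3888, 879 to 4038, 81 to 136, 107 to 171 and 861 to 2747 genes, and 717 to 2104 for the F-test. Arrays behind changes above 1.5 times are named beside each comparison.

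Gene-list calls numbered 89, or 10 with an estimated correlation and 33 with fry. Genes called in the same direction in 2 contrasts against WT numbered 166 summed over the 6 pairs, 440 at an unadjusted p under 0.01 (112.9 with simulated unchanged groups), and 93.8 with the WT arrays split between the contrasts. The gene-list tests with slide as a random block were not run.

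For the named genes, 6206 alternatives of a log2 change were computed: 5462 kept the side of the threshold and the direction, 719 lost the call, 3 gained it and 22 reversed. None of the 22 was called in the alternative that reversed it. Of the 22, 15 were of Rela: 0.032 with array weights (D361E against WT); -0.026 with quantile normalization, -0.228 without scaling, -0.048 with normexp and -0.027 as the lowest without 1 array, where the highest was 0.033 (1-361 against WT); -0.024, -0.365 and -0.105 with quantile normalization, no scaling and normexp (362-549 against WT). Further Rela values were -0.008 with normexp (1-361+362-549 against WT), 0.137 without scaling and 0.057 with normexp (1-361 against 362-549), -0.003 to 0.072 without 1 array (1-361+362-549 against 362-549), -0.015 with normexp (1-361 against D361E), and -0.106 without scaling and -0.072 with normexp (362-549 against D361E). For 1-361+362-549 against 1-361, Mylk turned to -0.302 with probes well above background on all arrays and Rpl31 to 0.051 with normexp. Against 362-549 without scaling, Ddb2, Pfkfb3, Atp5d and Xpc turned to 0.082, 0.034, 0.059 and 0.099, and against D361E Casp1 turned to 0.005.

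Other splits of the same arrays were counted after the results were seen. For D361E, 1-361 and 362-549 against WT, and 1-361 against D361E, only the real 1 of 35 splits gave as many genes. They numbered 74, 109, 109 and 156, with 1 as the highest other in each. The same held for 1-361+362-549 against WT (783 genes, highest other 47) and 362-549 against D361E (196 genes, highest other 29). That share is under 0.05 in each comparison alone, which argues against chance as the source of these counts. It is also the smallest share that 35 splits can give, and the splits treat arrays of different rounds as exchangeable. For 1-361+362-549 against D361E, 3 of 35 splits gave as many as 1478, so chance cannot be excluded there. The highest other split, with 5564 genes, set 1-361+362-549 replicates 1 and 2 with D361E replicate 4 against the rest, which points to a structure of the samples that does not follow the groups. Rounds of the title numbers may be part of it, although these arrays came from rounds 1, 2 and 4. For the F-test 3 of 100 groupings, the real one counted among them, gave as many as 1358 (highest other 4974). That share is under 0.05, but groupings across the groups gave more genes, so chance was not excluded. For the 3 comparisons of 3 against 3 arrays (96, 1701 and 2223 genes; 1 split each; highest other 0, 1 and 0), 10 splits are too few for a share under 0.05.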

Other observations

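The measured NF-kB target genes stood lower with 362-549 than with WT p65, also with an estimated correlation (adjusted p = 0.00365). For 1-361 and for both fragments that test gave 0.167 and 0.287, and 0.161 for 1-361 against 362-549, so a difference between the fragments was not shown. Tnfaip3 and Nfkbia, which restrain NF-kB and are induced by it, were called lower than in WT with each fragment and with both. The calls were lost with slide as a block with 1-361 and with both, where the changes stayed near those reported and the standard errors were larger. With both fragments against WT no gene list passed with an estimated correlation (lowest adjusted p = 0.132). No cells with an empty plasmid were analysed here, so whether WT p65 raised these genes or the fragments lowered them cannot be told. If each group is 1 transfected line, construct and line cannot be told apart in any contrast.

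Of the tests in this part, those of slide, of scaling, of an array state, of segments at single genes, of the probes of Macrod2 and Slc17a8 and of the fragments acting alike were chosen after the results were seen, and those of probe faults over the set, segments over the whole set, a low WT array and family probes were written before.

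The first pattern was the 783 genes called with both fragments against WT. A slide batch as the whole cause was not decided. The change with slide as a block was 0.99 of that without it (median, quartiles 0.94 and 1.05). It could hardly have fallen, as 762 of the 783 did not overlap. Over all genes the correlation within slides was -0.052. The fall to 242 calls went with a rise of the median standard error from 0.2 to 0.27. Scaling was tested first by the percent of called genes kept (bound 90%). It gave 89.02% with quantile normalization and 52.87% without scaling, and missed the bound. After that result the ratio of the changes was used instead, with a lowest 25th percentile of 0.77. Leaving out the scaling moved the median of all genes from 0.04 to 0.232, beside a median change of 1.06 in the called genes. The ratio could therefore hardly have fallen low. It shows that scaling does not make up the size of these changes, while the calls did depend on the scaling. An array state not tied to the construct cannot be told apart from an effect of the fragments: among 1238 genes called without 1-361+362-549 replicate 3, that array showed a median of 0.49 of the change in replicates 1 and 2 (85.54% in the same direction), and D361E replicate 4, with another construct, showed 0.35 (81.26%). An effect of the fragments stayed open and was not tested apart from a difference between transfected lines that arose in selection.

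The second pattern was a set of 14 large rises, each in 1 line with p65 fragments and called there against all 4 other groups (Nsd1, Col4a5, Epb41l3, Fndc4 and Macrod2 among them). A gained chromosomal segment as the cause of the set was argued against, since the 148 neighbours within 500 kb had a 75th percentile of change of 0.24 (2 rose, Fisher p = 0.715). Taken 1 by 1, that percentile was under 0.5 for 11 of the 14 genes, and a segment stayed open for the others, Cxcl3 (0.82), Serpinb6e (0.6) and an unnamed probe (0.53). Both rising neighbours were those of Cxcl3, Pf4 (2.01) and Ppbp (1.04), and a chemokine cluster can also rise through shared regulation. Whether a fragment acts alike with or without the other could not be decided by genes outside the pattern. With dim values held at the lowest signal well above background, 1 fragment raised 6 of them at least 8-fold. Of these, 100% were called lower by more than 2-fold with both than with that fragment. The falls ran from -6.39 to -1.83, and 4 of the 6 were globins, whose probes can share signal. But Cstdc4, Hbb-bh1, Hbb-bt, Hbb-b2 and an unnamed transcript of the 6 were also called higher than in WT with D361E (1.68 to 2.59). D361E is not a fragment, so their rise was not particular to a fragment. The explanation of a fragment acting alike was reworded, and its genes and measure were chosen anew, after its result. A fault of 1 probe was argued against for Macrod2 and Slc17a8, whose second probes rose by at least 8.05 and 4.39 beside at least 7.49 and 4.02 for the probes used. For the other genes it stayed open: 27.27% of the 11 other probes, in 5 genes, rose in fitted values (3, and 2 with dim values held as above). Of the 11, 7 were dim on every array and decide nothing, among them 4 of Macrod2, the upstream one of Nsd1 (used probe at least 8.76) and one of Fndc4 that overlaps the probe used (at least 3.85). Of 3 other probes of Gm5591 none rose by more than 0.57 with dim values held so (1.12 in fitted values), beside at least 2.74 for the probe used. A candidate explanation is a transcript that starts inside the gene, as near an inserted plasmid, which would differ from line to line and was not tested.

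The third pattern was the 14 genes higher in D361E, 1-361 and 362-549 than in WT, of which 6 were of the cystatin family and 4 were globins. A single low WT array as the cause was argued against, since at least 64.29% of the 14 genes (9) stayed called in all 3 comparisons whichever WT array was left out. Signal shared between family members stayed open: 0 of 15 pairs of the cystatin-family probes matched at 45 or more of 60 bases (18 to 40 matching, all offsets, widened after a first run). The bound written before was met, but it was wrong by design, because a probe may bind a relative's transcript away from that relative's own probe, and no transcripts were searched. With both fragments 1 of the 14 was called higher than in WT (Hbb-bt, 1.33). Cstdc4 and an unnamed transcript, dim on all arrays with both, were lower by at least 1.23 and 2.32, so a level low in WT alone would not account for these 2 genes. No biological explanation was tested.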
